A study of Mus musculus and Homo sapiens with 35 samples.

How the data were processed

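PolyA RNA-seq libraries were made from 21 mouse leukemia samples and 14 MOLM13 samples. The deposited tables, 1 per species, hold 35 columns of per-sample values, which are RPKM by the name the authors gave the tables. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.3a and featureCounts 1.6.3 were named, with the builds mm10 (GRCm38) and hg19 (GRCh37). The role of each tool and the gene lengths behind the RPKM are not given in the sources used here.

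Samples were grouped by sgRNA target and GFP fraction from the labels. The value columns carry a letter and a running number, and 0 of 35 such names occur in the labels of a sample. A match by column order or by the values themselves was ruled out before the data were examined. All 35 columns were therefore not used here, no library depth or replicate spread was computed, and the comparisons, tests and alternatives planned before the data were examined were not run. The columns used were the gene identifier, the gene symbol and the Entrez number of each row. They are annotations of the row that the authors deposited, and they belong to no sample.

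With Python 3.11.15 and pandas 2.3.3, the 27 gene lists fixed before the data were examined, holding 665 entries, were matched to the symbols of each table without regard to case, and older symbols were accepted where a list gave them. A gene that belongs to several lists counts once in each. Some lists, such as the erythroid markers with their globin genes, hold symbols used in only one of the species, so part of the entries could not match in the other and the totals over all lists understate the coverage. The position and exons of Pdxk were taken from GENCODE for GRCm38, the build named for mouse, and no human coordinates were taken.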

Results

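The study asked how loss of pyridoxal kinase changed the transcriptome of leukemia cells. Pyridoxal kinase, encoded by Pdxk in mouse and PDXK in human, phosphorylates forms of vitamin B6 on the way to pyridoxal phosphate, the cofactor of many enzymes of amino acid metabolism. PolyA RNA was sequenced from 35 samples, 21 from a mouse leukemia culture (MLLAF9-NrasG12D) and 14 from MOLM13, an established human acute myeloid leukemia line. The expression of no gene is reported here, because none of the 35 columns of expression values carries a name that occurs in the labels of a sample (0 of 35). The columns were not matched to samples by their order or by their values, so no fold change, test or depth per sample is given.

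The mouse samples were collected 7 days after infection or mock infection. The infecting vector linked the sgRNA to GFP. Cells of each infected culture were sorted into GFP+ and GFP- fractions. The labels give 6 GFP+ and 6 GFP- samples for sgRNAs against Pdxk. The control cultures comprised 2 GFP+ and 2 GFP- samples targeted at the mouse Rosa26 locus, and 2 GFP+ and 2 GFP- samples targeted at a human locus. Sample titles number the Pdxk and the human-locus cultures without saying whether the numbers stand for different sgRNAs or for replicates. A mock-infected culture gave 1 sample. In the labels, the knockout arm is the GFP+ fraction of the Pdxk cultures, and every other mouse sample is described as having intact Pdxk.

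The MOLM13 samples were collected 11 days after infection. The labels give 4 GFP+ and 4 GFP- samples for sgRNAs against PDXK, with 1 sample of each fraction for each of 4 differently named sgRNAs. The control arm comprised 3 GFP+ and 3 GFP- samples, with 1 of each from an sgRNA against mouse Rosa26, an sgRNA against a mouse chromosome 8 locus and a vector without an sgRNA. The design implies 5 comparisons per species, which are knockout against control among GFP+ cells, GFP+ against GFP- cells in the knockout and in the control cultures, the difference between those 2 changes, and knockout against control cultures among GFP- cells. None of them was made here.

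The targeted gene was listed in both tables. Mouse Pdxk (ENSMUSG00000032788) lies on chromosome 10 of GRCm38 from 78436744 to 78464975, on the minus strand. A protein-coding transcript of the gene, chosen by its name in the GENCODE annotation, has 11 exons, and other transcripts were not examined. Its start codon lies in exon 1 at 78464845 to 78464847, and its stop codon in exon 11 at 78440801 to 78440803. Exon 11 is 4170 bp long, of which 4060 bp were annotated as UTR together with the stop codon. Human PDXK was listed as ENSG00000160209. Odc1 (ENSMUSG00000011179), the polyamine enzyme ornithine decarboxylase, Got2 (ENSMUSG00000031672), the mitochondrial aspartate aminotransferase, and the transcription factor gene Myc (ENSMUSG00000022346) were listed in the mouse table. Their human counterparts ODC1 (ENSG00000115758), GOT2 (ENSG00000125166) and MYC (ENSG00000136997) were listed in the human table.

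The mouse table listed 19388 gene identifiers, of which 19140 (98.7%) had a symbol. The human table listed 25665 gene identifiers, of which 19160 (74.7%) had a symbol. Without regard to case, 11679 symbols occurred in both tables.

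Among gene lists fixed for this tissue and perturbation, 44 of 49 enzymes that use pyridoxal phosphate were matched in the mouse table and 43 of 49 in the human table. For polyamine metabolism, 20 of 21 entries were matched in mouse and 21 of 21 in human. All 28 entries for nucleotide biosynthesis and all 12 for heme biosynthesis were matched in both species. The p53 target list was matched for 27 of 30 entries in mouse and 30 of 30 in human. Other lists were matched in smaller part in at least one species. The mitochondrially encoded transcripts were matched for 6 of 13 entries in mouse and 13 of 13 in human. Unmatched in mouse were MT-ND3, MT-ND4L, MT-CYB, MT-CO2, MT-CO3, MT-ATP6 and MT-ATP8. Whether they were listed under other symbols was not checked. For secondary granule and neutrophil genes, 22 of 23 entries were matched in mouse and 16 of 23 in human. The unmatched human entries included symbols used for mouse genes only, but also LTF and CD177. Primary granule genes were matched for 11 of 14 entries in mouse and 14 of 14 in human. The unmatched mouse entries were AZU1, RNASE2 and RNASE3, and whether mouse genes carry these symbols was not checked. Lymphoid markers were matched for 12 of 20 entries in mouse and 14 of 20 in human, and stromal and fibroblast markers for 10 of 15 and 13 of 15. Megakaryocyte markers were matched for 11 of 13 entries in mouse and 9 of 13 in human, and mast cell and basophil markers for 7 of 12 in each. The erythroid list, whose globin entries mix mouse and human symbols, was matched for 8 of 20 entries in mouse and 7 of 20 in human. These numbers count entries matched by symbol, and no expression value was read for them. An unmatched entry may still be present in a row without a symbol or under a symbol not accepted here. A matched gene would also have had to pass the expression filter of the planned tests. Whether the authors had filtered the rows by expression is not known here, so no reason is given for an unmatched entry beyond the symbol use described.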

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

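The alternatives planned before the data were examined were not run, since each needs the value columns. No paired analysis was possible because the value columns carry no sample, culture or replicate name. Both alternatives for the list matching were chosen after seeing the data. With all accepted symbols, 602 of 665 list entries were matched in mouse and 611 in human. With the first symbol only, 585 and 603 were matched, and with rows that have an Entrez number only, 600 and 610.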
